A study of Folsomia candida with 18 samples.

How the data were processed

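Whole-animal RNA of the springtail Folsomia candida, a soil arthropod, was measured on 18 single-colour Cy3 arrays, 1 array per pool of 30 animals. The arrays formed 6 groups of 3: animals kept for 2, 7 or 14 days either in soil with decabromodiphenyl ether (BDE209, a brominated flame retardant) or in soil that had received the solvent only. Groups, days and replicate numbers were taken from the sample labels. The labels name each replicate a separate pool of animals, and the p-values therefore measure the spread between pools.

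The scanner files give a processed intensity for every spot, which Agilent Feature Extraction 10.7.3.1 had made, per the file headers, by background subtraction with spatial detrending and by detrending across the array. The submitters' processing notes name Agilent Feature Extraction 10.7. Each array carried 43795 spots that were not controls, holding 6175 probes with a length of 60 bases. Of these, 6118 probes were spotted 7 times and 57 were spotted 17 times. The deposited files also hold flags of another kind, neither intensities nor counts, that mark spots well above background, saturated spots and outlier spots. The deposited value table of the series holds log2 values for the same probes. Its columns correlated with their own array at 0.993 to 0.999, and no column correlated better with another array. The column medians of that table lay between 7.96 and 8.00, so its scale is log2 and its direction that of the signal, while the method that made the columns alike is not given in the sources used here. The number of columns in it that belonged to no sample was 0.

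Spots with an outlier flag were left out, which removed 1.01% to 1.97% of the spots per array. The log2 processed intensities of the spots of a probe were averaged, and the array's 75th percentile over its spots that were not controls was subtracted. No further background correction was applied. A probe counted as well above background on an array when more than 0.5 of its spots carried that flag, and it was tested when this held on at least 3 of the 18 arrays. This kept 5406 probes. Each probe is named by a transcript cluster. For 89 probes that name carries a suffix, which was taken to mark a further probe of the same cluster, and the probe with the highest mean signal represented the cluster, which left 5349 transcripts. No spot was saturated. Probes with an identical sequence, 36 probes sharing 17 sequences, differed by a median of 0.04 on the log2 scale within an array.

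Each of the 6175 probes is described as unknown in the files, and 0 of the 6086 cluster names matched the gene table of assembly ASM221717v1, so transcripts are reported by their cluster name and no genome position is given. The 26 gene lists fixed for detoxification, moulting, reproduction and other functions had 0 members for the same reason. No list could be tested, and the alternatives planned for the lists (camera with an estimated correlation, and fry) were not run.

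Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided). All 18 arrays entered a single fit with 6 group means and 12 residual degrees of freedom, and calls were made at a Benjamini-Hochberg adjusted p under 0.05 over all transcripts tested. The contrasts were exposed minus control at each time, their mean over the 3 times, the moderated F-test of whether the exposure effect differed between times, and the moderated F-test between times in control soil. Pairwise changes with time and the change with time in exposed animals came from the same fit. The sample groups, this design, the rule for naming transcripts and the first set of alternatives were chosen before the data were examined. The rule allowed 2 unnamed transcripts per direction and time, and those with the smallest p were taken. The 4 transcripts named for the control time course were picked in the same way after their values were seen.

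The script was tested on simulated data of 5349 transcripts, each with the SD that limma gave it in the fit of all arrays. The simulated noise had the same SD in all 6 groups and was independent between transcripts. The real pools differed in spread between groups, so the rates that follow check the script and do not measure its power in these data. For exposed minus control at 7 d it recovered 50% of the 100 transcripts changed by 2-fold and 82% of the 100 changed by 4-fold, with 10 false calls. For the differences between times in control soil it recovered 53% and 81%, with 8 false calls. The number of arrays limits the precision. The median 95% confidence interval of an exposure difference reached 0.57 log2 units to either side. It was the same at each time because the joint fit gives each transcript a single SD. The median SD between pools was 0.15 and 0.18 in control and exposed animals at 7 d, and 0.35 and 0.49 at 14 d. This width is therefore too narrow for 14 d and too wide for 7 d, and the SEs given below have the same limit.

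The alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization or median centring of the processed intensity, other filters on dim probes, the deposited value table, the replicate number, slide or scan date as a block, the 6 arrays of a time alone, array weights, other thresholds, the mean over the probes of a cluster, no intensity trend, an unmoderated equal-variance test per transcript, and leaving out each array. After the data were seen, 4 alternatives were added: leaving out the 6 arrays of 14 d, leaving out exposed 7 d replicate 1 together with control 14 d replicate 2, a replicate block within each time, and the array's log2 75th percentile as a covariate. The arrays came from 5 slides scanned on 2 days. Slide 1 held the 3 control arrays of 2 d and exposed 2 d replicate 1, and slide 2 held the other exposed arrays of 2 d. Slide 3 held the 3 control arrays of 7 d and exposed 7 d replicate 1, and slide 4 held exposed 7 d replicates 2 and 3 with control 14 d replicates 1 and 2. Slide 5 held control 14 d replicate 3 and the 3 exposed arrays of 14 d, and it was the only slide of the second day.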

Results

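The series asked how the transcripts of adult springtails respond to soil contaminated with decabromodiphenyl ether at 0.81 mg/kg of dry soil. Pools of 30 animals, 23 days old, were kept in contaminated or solvent control soil, and 3 pools per soil were measured after 2, 7 and 14 days. Animals from contaminated soil are called exposed here. Between 77.5% and 87.1% of the 6175 probes were well above background on an array, and the 75th percentile of the processed signal ranged from 530 in control 14 d replicate 1 to 1734 in control 2 d replicate 3. Levels are given as log2 signal minus the array's 75th percentile.

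The first principal component held 46.7% of the variance and set 5 of the 6 arrays of 14 d, together with exposed 7 d replicate 1, apart from the other arrays. Control 14 d replicate 2 lay among the earlier arrays. The median SD between pools was 0.16 log2 units in control and 0.25 in exposed animals at 2 d, 0.15 and 0.18 at 7 d, and 0.35 and 0.49 at 14 d. The array signal also differed most at 14 d, where the 75th percentile was 530, 885 and 1156 in the control pools and 590, 567 and 1304 in the exposed pools.

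**Figure D1:**
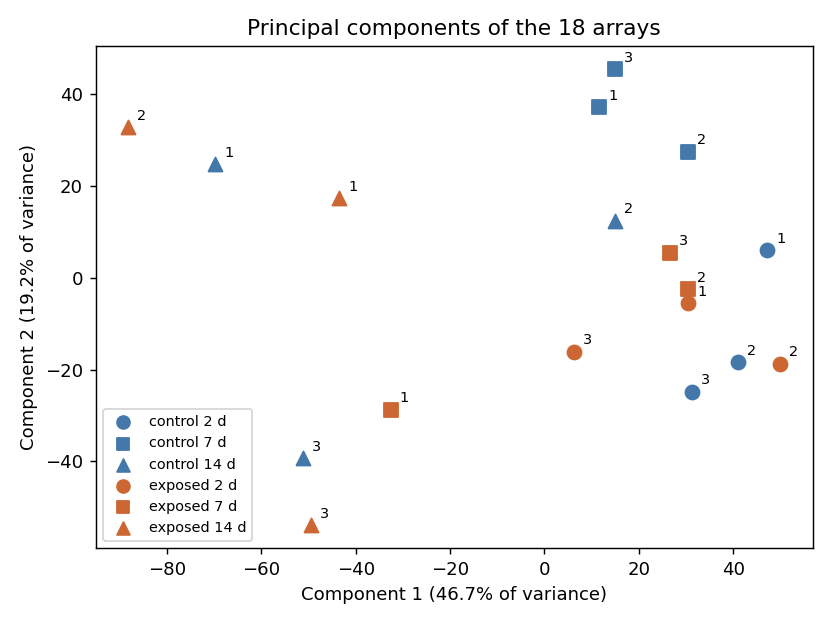
Scores of the 18 arrays on the first 2 principal components of 5349 transcripts, in log2 units; the colour gives the soil, the symbol the time and the number the replicate. The components held 46.7% and 19.2% of the variance, and exposed 7 d replicate 1 at -32.6 lay on the side of the later arrays.

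At 7 d, exposed pools stood apart from control pools in a large share of the transcripts. In 2690 of 5349 transcripts (50.3%, where chance gives 10%) all 3 exposed pools lay above or all below the 3 control pools, with 1531 above and 1159 below. Fcc06125 measured -2.32 ± 0.12 (SD, n = 3) in exposed and -3.06 ± 0.12 (SD, n = 3) in control animals, a log2 difference of 0.75 (SE 0.12). Fcc01859 measured 1.03 ± 0.21 against 0.11 ± 0.26 (SD, n = 3 each), a difference of 0.92 (SE 0.16). On the lower side, Fcc04355 measured -4.73 ± 0.18 against -3.70 ± 0.19 (SD, n = 3 each), a difference of -1.04 (SE 0.22), and Fcc00695 measured -0.96 ± 0.30 against 0.04 ± 0.18 (SD, n = 3 each) (SE of the difference 0.23). With normexp and quantile normalization the difference was 0.50 for Fcc06125 and -0.48 for Fcc04355. In all 4 of these transcripts each exposed pool lay on the same side of each control pool.

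With all 18 arrays in the fit, limma called 0 transcripts at 7 d. At an unadjusted p under 0.05 there were 787 higher and 446 lower transcripts, and the smallest adjusted p from limma was 0.0802, which these 4 transcripts shared. With the 6 arrays of 7 d fitted alone, limma called 958 transcripts higher and 566 lower in exposed animals, the median SD being 0.18 log2 units in that fit and 0.32 in the fit of all arrays. The 4 named transcripts then had adjusted p-values from limma between 0.0149 and 0.0195. Over all alternatives that of Fcc06125 ranged from 0.00122 to 0.308, the lower end with array weights, whose estimation did not converge. The called differences were mostly small, with a median size of 0.62 log2 units, and 279 of the 1524 calls reached 2-fold. The equal-variance test of each transcript called 665 higher and 317 lower. Calls also appeared in the joint fit once a single exposed pool of 14 d was left out: limma called 446 higher and 109 lower without replicate 3, and 29 higher and 4 lower without replicate 2. With all 18 arrays and the array signal as a covariate it called 545 higher and 63 lower. With slide as a block, the 7 d difference rests on exposed replicate 1 alone, the only exposed pool on slide 3 with the 3 control arrays. The differences of that pool were 0.76 for Fcc06125, 1.04 for Fcc01859, -0.95 for Fcc04355 and -0.84 for Fcc00695. They are no second estimate from all pools, and a single exposed pool is too few for a test within the slide.

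**Figure D2:**
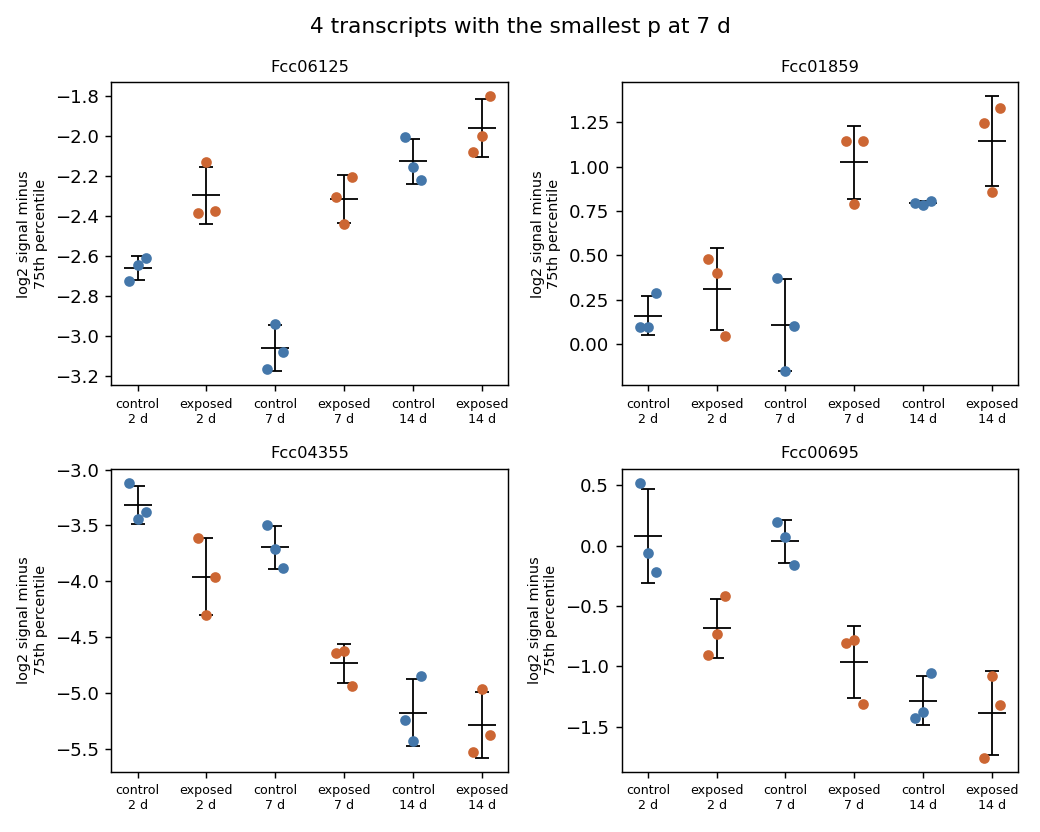
Log2 signal minus the array's 75th percentile of the 4 transcripts with the smallest p at 7 d; dots are single pools, horizontal bars the mean and whiskers the SD of 3 pools, blue for control and orange for exposed animals. At 7 d Fcc06125 averaged -2.32 in exposed and -3.06 in control animals, and at 14 d it averaged -1.96 and -2.13.

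The probe of Fcc06125 had the sequence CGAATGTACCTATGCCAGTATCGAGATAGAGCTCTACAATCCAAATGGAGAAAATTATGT, that of Fcc01859 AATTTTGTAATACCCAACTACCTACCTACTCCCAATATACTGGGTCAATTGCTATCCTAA, that of Fcc04355 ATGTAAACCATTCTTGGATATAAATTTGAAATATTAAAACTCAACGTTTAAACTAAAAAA, and that of Fcc00695 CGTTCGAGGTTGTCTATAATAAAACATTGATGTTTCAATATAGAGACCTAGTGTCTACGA. These transcripts were picked for their small p at 7 d, and for each the F-test of a differing effect between times had an adjusted p from limma of 0.773. The exposure difference of Fcc06125 was 0.36 at 2 d and 0.17 at 14 d (adjusted p from limma 0.531 and 1), and that of Fcc04355 was -0.65 and -0.11 (adjusted p from limma 0.536 and 1). In control animals Fcc04355 fell from -3.70 at 7 d to -5.17 at 14 d, below the -4.73 of exposed animals at 7 d.

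At 2 d, fewer transcripts separated the soils: all exposed pools lay above all control pools in 543 transcripts and below in 434, together 18.3% against 10% by chance. Fcc02802, a strongly expressed transcript, measured 0.83 ± 0.60 in exposed and 3.04 ± 0.30 in control animals (SD, n = 3 each), a log2 difference of -2.21 (SE 0.45, adjusted p from limma 0.442). Fcc01730, among the brightest 1% of the array, measured 4.64 ± 0.88 against 6.68 ± 0.20 (SD, n = 3 each), a difference of -2.04 (SE 0.42, adjusted p from limma 0.442). At 2 d, 1 transcript was well above background in all exposed and no control pools, and 22 in all control and no exposed pools. These counts were 29 and 1 at 7 d, and 0 and 2 at 14 d. The array's 75th percentile ranged from 1372 to 1734 in control and from 1002 to 1519 in exposed pools of 2 d. For 7 d the ranges were 732 to 1020 and 887 to 1205. An effect of exposure on these counts was not told apart from array signal. Fcc05636 was well above background in the 3 exposed pools of 2 d, where it measured -5.84 ± 0.39 (SD, n = 3, adjusted p from limma 0.442), and in no other pool. Its difference from the controls rests on background, and with normexp and quantile normalization it was 0.30 on the log2 scale. Fcc03186 was well above background in 3 exposed and 2 control pools at 2 d and measured -5.73 ± 0.39 against -7.25 ± 0.22 (SD, n = 3 each; adjusted p from limma 0.457), a log2 difference of 1.52 that was 0.23 with normexp and quantile normalization.

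Neither direction held a call at 2 d: limma called 0 transcripts, with 152 higher and 214 lower at an unadjusted p under 0.05. The 6 arrays of 2 d alone gave 0 calls by limma and 0 by the equal-variance test, with 340 higher and 246 lower at an unadjusted p under 0.05 in the latter. For 3499 transcripts (65.4%) the 95% confidence interval of the difference lay within 2-fold in either direction. With slide as a block, the 2 d difference rests on exposed replicate 1 alone, the only exposed pool on slide 1 with the 3 control arrays. A single exposed pool is too few for a comparison within the slide.

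At 14 d, exposed and control pools overlapped in nearly all transcripts. All exposed pools lay above all control pools in 74 transcripts and below in 97, together 3.20%, under the 10% that chance gives. Fcc01734 measured -6.99 ± 0.38 in exposed and -5.08 ± 0.89 in control animals (SD, n = 3 each), a log2 difference of -1.91 (SE 0.37, adjusted p from limma 0.335), and it was well above background in 1 of the 3 exposed pools. Fcc01440, likewise well above background in 1 exposed pool, differed by -2.28 (SE 0.46, adjusted p from limma 0.335). The sizes of both differences rest on exposed pools near background, and with normexp and quantile normalization they were -0.40 and -0.47. On the higher side, Fcc05090 differed by 2.19 (SE 0.68) and Fcc01550 by 0.44 (SE 0.14), each with an adjusted p from limma of 1. The difference of Fcc05090 was 1.28 with normexp and quantile normalization. The level of Fcc01734 was also lower in exposed animals at 7 d, by a difference of -1.27 (adjusted p from limma 0.104).

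The joint fit gave 0 calls by limma at 14 d, with 38 higher and 103 lower at an unadjusted p under 0.05. The equal-variance test also gave 0 after adjustment, with 33 higher and 36 lower at an unadjusted p under 0.05. Without exposed 14 d replicate 3, limma called 21 transcripts lower. With slide or scan date as a block, the 14 d difference rests on control replicate 3 alone, the only control pool on slide 5. For Fcc01734 it was -2.94 in both fits, where that control pool measured -4.05, the highest of the 3 control pools of 14 d. Over all alternatives the adjusted p from limma of Fcc01734 ranged from 6.27e-05 to 1. The lower end came with array weights, whose estimation did not converge. With the array signal as a covariate limma called 1 lower, Fcc01440 (difference -2.16, adjusted p from limma 0.0242, with the same range over all alternatives). Slide 5, which held the 3 exposed arrays, held a single control pool, too few for a comparison within the slide.

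Averaged over the times, limma called 0 transcripts, with 506 higher and 502 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0574. Fcc06125 was higher by 0.43 (SE 0.07) and Fcc01734 lower, with a mean difference of -1.21 (SE 0.21), each with an adjusted p from limma of 0.0574. The 14 d part of the latter rests on pools near background. The smallest p in each direction belonged to Fcc02874 (0.44, SE 0.07) and Fcc01065 (-1.26, SE 0.21), with the same adjusted p from limma. Fcc01065 was well above background in 0 of the exposed pools of 14 d. Calls on average depended on single pools of 14 d: limma called 51 higher and 25 lower without control replicate 1, 141 and 209 without exposed replicate 2, and 45 and 40 without exposed replicate 3. It also called 29 higher and 25 lower with scan date as a block, and 638 and 336 with the array signal as a covariate. With scan date as a block, the 14 d part of the mean rests on control replicate 3 alone.

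No transcript was shown to respond differently between times. The F-test of limma called 0, with 202 at an unadjusted p under 0.05 and a smallest adjusted p of 0.773. Across transcripts, the exposure differences correlated at 0.21 between 2 d and 7 d, 0.29 between 2 d and 14 d and 0.25 between 7 d and 14 d (Pearson), with Spearman values of 0.19, 0.25 and 0.20. The times shared no arrays, and transcripts are not independent replicates. With no calls at any time, no overlap of calls could be counted. These correlations depended on single pools and on the model. That between 7 d and 14 d was -0.16 without exposed 14 d replicate 3, -0.01 without exposed 7 d replicate 1 and 0.56 without exposed 14 d replicate 2. That between 2 d and 7 d was -0.04 without control 2 d replicate 1, and that between 2 d and 14 d was 0.02 without exposed 2 d replicate 3. The correlation between 7 d and 14 d was -0.33 with slide and -0.41 with scan date as a block. In both fits the 14 d difference rests on control replicate 3 alone, and with slide the 7 d difference rests on exposed replicate 1 alone. With the array signal as a covariate the correlations were 0.48 between 2 d and 7 d, 0.09 between 2 d and 14 d and 0.50 between 7 d and 14 d.

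The comparison between times asked how animals in control soil changed over the experiment. In control soil, 1157 transcripts differed between the 3 times by the F-test of limma. Of these, 431 rose throughout, with a median increase of 1.09 log2 units from 2 d to 14 d, 248 fell throughout, with a median change of -1.30, 229 were highest at 7 d and 249 lowest at 7 d. Between 2 d and 14 d, 670 transcripts were higher and 378 lower. Fcc05550 rose from -4.62 ± 1.09 to 0.78 ± 0.86 (SD, n = 3 each), a log2 change of 5.40 (SE 0.61, adjusted p from limma 0.00049), and Fcc00522 rose by 3.34 (SE 0.37, adjusted p from limma 0.00049). Fcc04198 fell from -0.24 ± 0.66 to -6.43 ± 0.54 (SD, n = 3 each), a change of -6.20 (SE 0.59, adjusted p from limma 0.000244), and Fcc02476 had a change of -4.35 (SE 0.43, adjusted p from limma 0.000244). At 14 d these falling transcripts were each well above background in 1 of the 3 control pools, and in all 3 at 2 d, so the sizes of their changes rest on pools near background. With normexp and quantile normalization the changes were -3.45 and -1.47, that of Fcc00522 was 2.07 and that of Fcc05550 was 3.96. The probe of Fcc05550 had the sequence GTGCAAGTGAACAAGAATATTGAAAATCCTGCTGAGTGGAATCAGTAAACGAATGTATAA, that of Fcc00522 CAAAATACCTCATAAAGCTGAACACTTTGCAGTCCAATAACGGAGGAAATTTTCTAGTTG, that of Fcc04198 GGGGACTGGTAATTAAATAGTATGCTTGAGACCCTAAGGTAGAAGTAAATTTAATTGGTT, and that of Fcc02476 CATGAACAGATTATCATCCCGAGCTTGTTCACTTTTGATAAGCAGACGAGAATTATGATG.

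Exposed animals went through a similar change from 2 d to 14 d. Between these times, limma called 891 transcripts higher and 616 lower in exposed animals. Of the 670 transcripts higher in control animals, 563 were also higher in exposed animals, where independent lists would share 112, and of the 378 lower ones 282 were shared against 43.5. The number called in opposite directions was 0, where independent lists would share 140.1, and it was 6 without control 14 d replicate 3. The changes correlated at 0.88 (Pearson) and 0.85 (Spearman) across transcripts, with no array in common. Slide 1 held arrays of both soils at 2 d, and slide 5, scanned on the second day, held arrays of both at 14 d. An effect of slide, scan or array signal common to both soils could add to this agreement and was not told apart from time. The 431 transcripts that rose throughout in control animals all had a higher mean at 14 d than at 2 d in exposed animals too, with a median change of 1.09, and 351 of them were called by the F-test in exposed animals. From 2 d to 7 d, 411 of these 431 had the same direction in exposed animals. Of the 229 transcripts highest at 7 d, 177 had the same direction over that interval and 98 were called in exposed animals. Of the 249 lowest at 7 d, 132 (53.0%) had the same direction and 70 were called. From 2 d to 14 d the direction was the same for 216 of the 229 and 213 of the 249. The difference between these classes was not tested. The agreement was looser from 2 d to 7 d, where the correlation was 0.43, and limma called 82 higher and 29 lower transcripts in control but 9 and 6 in exposed animals. Fcc05550 was 5.18 higher at 14 d than at 2 d in exposed animals and Fcc04198 had a change of -5.00 (adjusted p from limma 0.000189 and 0.000184).

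**Figure D3:**
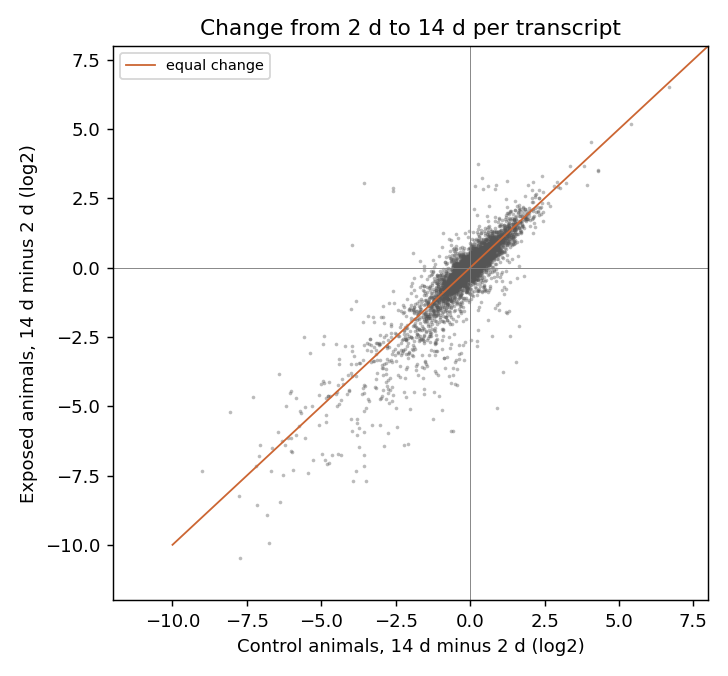
Log2 change from 2 d to 14 d of 5349 transcripts in control animals (horizontal axis) and in exposed animals (vertical axis); each dot is a transcript and the line marks equal change. The changes correlated at 0.88.

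The number of calls depended on single pools. The 1157 calls between times in control soil became 771, 546 and 645 without control 2 d replicates 1, 2 and 3, 754 and 725 without control 7 d replicates 1 and 3, 650 without control 14 d replicate 1, and 2111 without exposed 14 d replicate 3. The change from 2 d to 14 d in control animals gave 272 higher and 237 lower calls without control 14 d replicate 1, 386 and 176 without control 2 d replicate 1, 358 and 237 without control 2 d replicate 2, 426 higher without control 2 d replicate 3, and 1007 and 570 without exposed 14 d replicate 3. The 563 higher and 282 lower calls shared with exposed animals became 364 and 156 without control 2 d replicate 1, 329 higher without control 2 d replicate 2, 266 higher without control 14 d replicate 1 and 933 higher without exposed 14 d replicate 3. With scan date as a block they were 16 and 20, but that fit takes the effect of the scan day from 1 pool. This pool is control 14 d replicate 3, set against control 14 d replicates 1 and 2. Over all alternatives except array weights the shared calls reached 933 and 491. In exposed animals there were 520 higher without exposed 14 d replicate 2, and 1412 higher and 1070 lower without replicate 3. No slide held control arrays of more than 1 time, so a change with time could not be estimated within slides in control animals. With scan date as a block the calls in exposed animals from 2 d to 14 d were 16 higher and 23 lower, with the same limit of 1 control pool. With median centring the control calls were 725 higher and 225 lower (76.3% higher in place of 63.9%), since that scaling moved the median change of all transcripts from -0.001 to 0.15. Quantile normalization gave 1007 higher and 401 lower, with a median change of 0.11, the deposited value table gave 1012 and 399, and the array signal as a covariate gave 736 and 640.

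Within groups, 61 transcripts had an SD over 3 log2 units between pools, a limit chosen after the data were seen. Across all arrays their levels had a median correlation of 0.65. This value includes differences between groups and does not measure how far the transcripts moved together within groups. The median level of the 61 transcripts was 2.41, 1.47 and 1.03 in the control pools of 2 d and 1.51, 1.59 and 1.27 in those of 7 d. At 14 d it was -6.28, 2.13 and -6.69 in the control pools and -4.15, -7.31 and -6.33 in the exposed pools. Exposed pools of 2 d measured 0.96, 2.55 and -2.63, and those of 7 d measured -6.31, 2.01 and 2.31. The array medians thus ranged over 9.86 log2 units, the median range of a single transcript was 10.9, and pools of one group lay at both levels. The low levels reach background, since 15 of the 61 transcripts were well above it in exposed 14 d replicate 2.

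**Figure D4:**
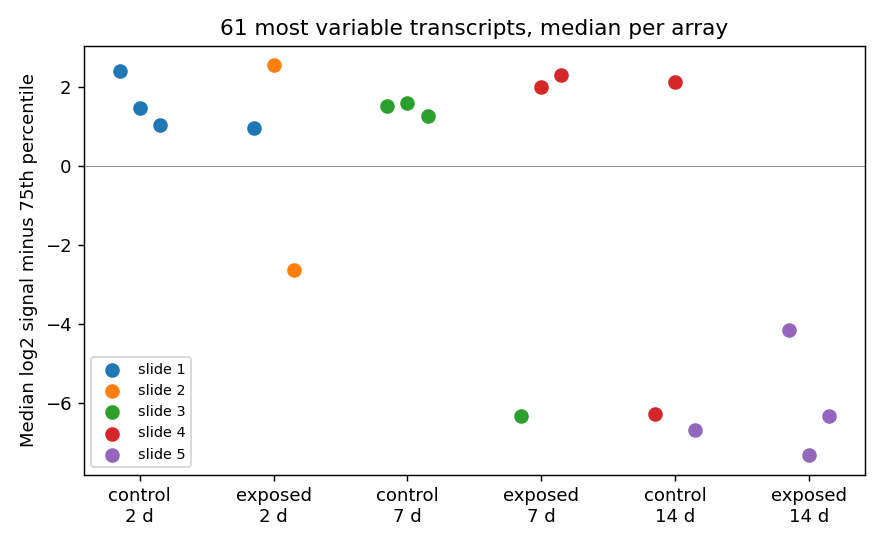
Median log2 signal minus the array's 75th percentile over the 61 transcripts with the largest SD between pools of a group; each dot is an array, coloured by slide. In control animals of 14 d and exposed animals of 7 d, 1 pool lay more than 8 log2 units from another of its group.

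None of the transcripts could be placed in the gene groups set out for detoxification, oxidative stress, cuticle and moulting, reproduction, nervous system, digestion or immunity, because the probes carry no descriptions and the 26 lists had 0 members.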

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

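The 4 alternatives added after seeing the data were the array signal as a covariate, the fit without the arrays of 14 d, the fit without exposed 7 d replicate 1 and control 14 d replicate 2, and the replicate block within each time. Under normexp with quantile normalization, quantile normalization, median centring, no filter, the deposited value table, the mean over probes and the fit without those 2 arrays, limma called 0 transcripts for every exposure contrast. The fit as reported also called 0, with 366 transcripts at 2 d, 1233 at 7 d, 141 at 14 d and 1008 on average at an unadjusted p under 0.05. For the changes that follow the cause was not tested. With only probes well above background on all 18 arrays, 33 transcripts were higher and 22 lower on average. With slide or scan date as a block, the 14 d difference rests on control replicate 3 alone, so calls at 14 d are not counted there. With slide, the differences at 2 d and 7 d each rest on exposed replicate 1 alone. Scan date as a block gave 29 higher and 25 lower on average, a mean whose 14 d part rests on that control pool. Without an intensity trend, 6 were higher and 4 lower on average.

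The 7 d arrays alone gave 958 higher and 566 lower, the equal-variance test 665 and 317, and the fit without the 14 d arrays 975 and 441. The array signal as a covariate gave 1 lower at 2 d, 545 higher and 63 lower at 7 d, 1 lower at 14 d, 638 and 336 on average, and 1975 between times in control soil. Array weights, whose estimation did not converge (weights from 0.071 to 29.6), gave 352 higher and 239 lower at 2 d, 1303 and 907 at 7 d, 1617 and 1463 at 14 d, 1240 and 950 on average, 3023 for an effect that differs between times and 4237 between times in control soil. Requiring a 2-fold change as well left 579 between times in control soil. At an unadjusted p under 0.05 with a 2-fold change there were 30 higher and 63 lower at 2 d, 125 and 84 at 7 d, 2 and 54 at 14 d, 6 and 57 on average, and 96 whose effect differed between times.

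Leaving out each array in turn gave 0 to 446 higher and 0 to 109 lower at 7 d, 0 to 21 lower at 14 d, 0 to 141 higher and 0 to 209 lower on average, and 546 to 2111 between times in control soil. The calls at 7 d came without exposed 14 d replicate 2 (29 higher, 4 lower) or replicate 3 (446 and 109), and those at 14 d without replicate 3. Those on average came without control 14 d replicate 1 (51 and 25), exposed 14 d replicate 2 (141 and 209) or replicate 3 (45 and 40). Between times in control soil there were 771, 546 and 645 calls without control 2 d replicates 1, 2 and 3, 754 and 725 without control 7 d replicates 1 and 3, 650 without control 14 d replicate 1 and 2111 without exposed 14 d replicate 3. The correlation of exposure differences ranged from -0.037 to 0.369 between 2 d and 7 d, 0.018 to 0.377 between 2 d and 14 d and -0.162 to 0.557 between 7 d and 14 d. The 16 transcripts named for a single time or for the control time course kept their direction under every alternative that gave a value, but not their size. Under normexp with quantile normalization, whose offset of 50 by construction shrinks changes of dim probes, the log2 change was 0.30 for Fcc05636, 0.23 for Fcc03186, -0.48 for Fcc04355, 1.28 for Fcc05090, -0.40 for Fcc01734, -0.47 for Fcc01440, 2.07 for Fcc00522, -3.45 for Fcc04198 and -1.47 for Fcc02476. That of Fcc05550 was 3.96. With slide or scan date as a block the log2 change of Fcc01734 at 14 d was -2.94, which rests on control replicate 3 alone. The correlation between 7 d and 14 d was -0.331 with slide and -0.405 with scan date, and its 14 d side rests on that same pool. With slide, its 7 d side rests on exposed 7 d replicate 1 alone. Deviations from the group means correlated between -0.34 and 0.613 for control and exposed pools of the same time and replicate number. Pools of different numbers were not compared, so whether the replicate numbers pair the pools was not settled. With the replicate block limma called 1004 between times in control soil and 0 for every exposure contrast, with 820 higher and 429 lower at 7 d at an unadjusted p under 0.05. Dim transcripts are limited by background, since 4504 clusters were well above it on all 18 arrays.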

Other observations

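The tests of the 14 d signal split and of the switching transcripts, and the share of each left-out control at 7 d, were chosen after the result was seen.

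Fitted alone, the 7 d arrays gave calls that the joint fit did not. The real split of the 6 arrays gave 1524 calls and the highest of the other splits 3; these were 10 splits, the real one being the 1 with as many calls, which is too few for a share under 0.05. The values that were compared go against slide as the whole cause but come from a single pool, which cannot exclude it: in 1229 transcripts called between exposed replicates 2 and 3 on slide 4 and the controls on slide 3, exposed replicate 1, which shared slide 3 with the controls, showed a median share of 0.799 of the difference (quartiles 0.556 and 1.04) and lay on the same side in 97.7% of them, where a share over 0.5 had been set beforehand as going against slide. The same controls entered the calls and the share, which raises the share; with each control left out in turn and 1851 to 2026 transcripts taken at an unadjusted p under 0.05, that control had a median share between -0.153 and 0.23 and exposed replicate 1 one between 0.797 and 0.833. An exposure effect at 7 d may be present and remains a hypothesis, with differences in the state of the pools untested.

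The array medians of the 61 switching transcripts ranged over 9.86 log2 units, or 9.23 with values raised to the lowest signal well above background on their array. Slide is argued against, because the array medians on slide 4 alone ranged over 8.59 log2 units, and so is a difference in hybridisation or scanning of whole arrays, because the largest range of any of the 10 spike-in controls was 0.238 of the latter range. An exchange of labels between exposed 7 d replicate 1 and control 14 d replicate 2 stays open: it would lower the sum of squares within groups to 78.6% of its value, the lowest of 135 exchanges, but that of control 14 d replicate 1 and exposed 14 d replicate 3 would lower it to 80.4%. No biological explanation was tested.

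Another split of the 14 d arrays called far more transcripts than the real one, which points to a structure among these pools. The 3 arrays with the lowest signal (75th percentiles from 530 to 590; control replicate 1 and exposed replicates 1 and 2) differed from the 3 with the highest (885 to 1304) in 2711 transcripts, 1551 higher and 1160 lower, where the real split gave 0. In the 12 arrays of 2 d and 7 d, which did not define this axis, the position along it followed the array signal within groups (Pearson r = -0.851, exact permutation p = 0.0139; Spearman rho = -0.853, exact permutation p = 0.0116; r = -0.762 without the 2 arrays farthest from the median signal). The shape of the signal distribution as the cause is argued against, since quantile normalization left 83.4% of the calls. The signal may reflect RNA quality, labelling yield or the state of the animals, and an exchange of labels between control replicate 1 and exposed replicate 3, which would turn this split into that between the soils, also stays open.

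For the real splits in the joint fit, limma called 0 at 2 d, 7 d and 14 d, and 10 of 10 splits gave as many calls at each time, with 366, 1233 and 141 transcripts at an unadjusted p under 0.05 in the real splits. The highest of the other splits gave 0, 0 and 2711 calls, and 4.47%, 2.0% and 56.7% of the transcripts at an unadjusted p under 0.05, where the real splits gave 6.84%, 23.1% and 2.64%. These 10 splits are too few for a share under 0.05. On average over the times, 10 of 100 drawn splits gave as many as the 1008 transcripts at an unadjusted p under 0.05 (highest of the others 2904), so chance was not excluded. Any split gives at least 0 calls, so nothing follows from the 100 of 100 draws that gave as many as the 0 calls by limma on average (highest of the others 2549) and for an effect that differs between times (highest of the others 480, with 202 transcripts at an unadjusted p under 0.05 in the real assignment). For the 1157 calls between times in control soil, 1 of 100 drawn splits, the real one, gave as many (highest of the others 314), and chance was excluded. The draws mixed arrays of different slides, and no slide held control arrays of more than 1 time. An effect of slide or array signal was therefore not told apart from time by this test.

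The exposure difference at 7 d had no relation of a common sign to the control change from 2 d to 14 d across transcripts (Pearson 0.081, Spearman -0.079). Without exposed 7 d replicate 1 the values were -0.213 and -0.204, and for replicate 1 alone they were 0.37 and 0.026, so there was too little relation with all pools to assign to that pool.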
